A study of Mus musculus with 3 samples.

How the data were processed

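Small RNA of mouse epididymis was sequenced from 1 wild-type library and 2 libraries of mice lacking Alkbh3, called knockout 1 and knockout 2 after the numbers in their labels. ALKBH3 is a demethylase that removes 1-methyladenosine and 3-methylcytidine from tRNA. Per the labels' protocols, 100 µg of total RNA was run on a 15% denaturing gel, RNA of 15 to 50 nt was cut out of the gel and recovered, and libraries were made with a commercial small RNA kit. The labels give the knockout libraries different numbers but do not say whether they came from separate animals. The p-values measure the spread between these libraries, pooled over features of like abundance, which may be technical.

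The authors deposited 3 kinds of table, all holding read counts that were not normalized. The first deposited table gives the count of reads per library in 5 RNA classes (rRNA, tRNA, snoRNA, miRNA and mRNA). The second gives the count per tRNA gene for 446 nuclear tRNA genes, of which 36 had 0 reads in all libraries. The third kind, 1 deposited table per library, gives each tRNA gene's position, length and strand, the count of reads in each of 2 read classes, and a list of read lengths with their counts. Per the submitters' processing notes the genome build was mm10 and cutadapt was used, with no version given. The aligner, the counting tool and the treatment of reads that match several tRNA gene copies are not given in the sources used here. The deposited length lists, whose unit was recorded as other because each cell holds pairs of a length and a count, summed to the class counts in every gene, with 0 exceptions, and listed counts down to 1.

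The 2 read classes of the per-library tables carry no description in the sources used here. If they were the 5′ and 3′ parts of a tRNA cut once, their most frequent lengths should sum to the tRNA length. This held within 3 nt in 31 of 121 genes with at least 50 reads in both classes, so the classes were left unnamed and are called the first and the second class, in the order of the columns. Coordinates in the per-library tables were taken as 1-based mm10 positions. Of 413 genes with coordinates, 368 had the start and end of a RefSeq tRNA gene of the same assembly and 374 overlapped one (90.6%). Overlap with other genes was taken from GENCODE. Sequences were not analysed here.

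Depth was the sum over the 5 classes: 15107055 reads in the wild type, 15411457 in knockout 1 and 21169908 in knockout 2. The tRNA class held 6754440, 5623960 and 8063516 reads in the same order. The tRNA gene table summed to 59.4%, 59.4% and 59.1% of that class and the per-library tables to 95.5%, 94.1% and 94.2%. The reason for the difference between the tables is not given in the sources used here. Shares carry Wilson 95% intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules.

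Counts of the gene table were summed per amino acid and anticodon, because copies of a tRNA gene are nearly identical and reads cannot be assigned to single copies. This gave 56 sums, 50 of them above 0. Gene rows were also tested as deposited. For fragments, counts of the per-library tables were summed per anticodon, read class and read length, giving 2336 features, since the tables list no read sequences. Knockout was compared with wild type by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with the 5-class total as library size, no composition factor, edgeR's filterByExpr, and Benjamini-Hochberg adjustment at 0.05. The knockout libraries leave 1 residual degree of freedom, and the lone wild-type library is assumed to vary like them. In each main fit edgeR's prior degrees of freedom were infinite. A feature's own spread thus had no weight, and its p-value rests on the trend over features of like abundance. The standard error of a log2 fold change was its size divided by the root of the F statistic. Folds were fitted by the same model. Fixed anticodon lists were tested with camera on voom values (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one. The preset value is an assumption. The estimate rests on 1 residual degree of freedom, so its p-values cannot decide whether a list result holds. Shares were compared without a test.

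The design, the tests, the lists, the naming rule and most alternatives were fixed before the data were examined. The plan expected fragments joined by sequence or by another identity given in the tables, and the sums per anticodon, read class and length were chosen once the tables were seen. The rule named, per table, the 10 features higher and the 10 lower with the largest log2 fold change among those past the threshold with both knockout libraries on the same side of the wild type, filled to 5 per direction with features of at least 100.0 RPM (reads scaled to the 5-class total) where fewer passed, plus the 10 most abundant. For single genes and for fragments these numbers were 5, 5 and 5. Alternatives were TMM factors, column sums as library size, DESeq2 1.42.0, no filter, a filter of at least 100 reads in 2 libraries, a robust prior, leaving out each knockout library (a log2 ratio with a prior count of 2 and no test), other denominators of the tRNA share, and a 30 to 36 nt class widened to begin at 28 nt. Chosen after seeing the data were a library size without miRNA reads, a fit without a dispersion trend, and counts from the per-library tables.

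The test was checked on simulated counts in 10 draws per table, with folds of 2 and 4. For anticodon sums (45 features) it called 40% of 2-fold and 57.5% of 4-fold changes, and 6.52% of calls were false. For genes (348 features) the values were 31.4%, 80% and 1.79%, and for fragments (834 features) 3.45%, 24.0% and 2.56%. The counts were drawn with the same dispersion for all features of a table and for both genotypes. The check thus cannot show false calls that come from the dispersion trend or from a wild type that varies more. Tables were handled with pandas 2.3.3 under Python 3.11.15, intervals computed with SciPy 1.17.1 and plots drawn with matplotlib 3.10.9.

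Alkbh3 mRNA was not analysed here, because mRNA enters only as a class total, so the genotypes rest on the labels. Lists of microRNAs and of mitochondrial tRNAs fixed in advance were not analysed here, since the tables used name none of their members. The rows for suppressor and undetermined tRNAs held 0 reads and were not tested.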

Results

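Small RNA from the epididymis, the duct in which sperm mature, was profiled in 1 wild-type library and 2 Alkbh3 knockout libraries to compare the small RNA of the 2 genotypes. ALKBH3 removes methyl groups from 1-methyladenosine and 3-methylcytidine, modified bases of tRNA. The wild-type library held 15107055 reads over 5 RNA classes, knockout 1 15411457 and knockout 2 21169908, of which 6754440, 5623960 and 8063516 were tRNA reads. The tRNA gene table held 4014098, 3340218 and 4766609 reads in the same order, over 403, 397 and 398 tRNA genes with reads. Counts over tRNA genes differed between the knockout libraries, with a chi-square of 43.3 per degree of freedom (715 and 856 between the wild type and either of them), so they are not 1 set of reads entered again. This does not show that they come from separate animals, which the tests here assume. Means over the knockout libraries are given with the SD and n = 2. The wild type has no replicate.

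The first question was whether the classes of small RNA were present in other proportions. tRNA reads made up 44.7% of the wild-type library (95% Wilson interval 44.69 to 44.74%) and 36.5% and 38.1% of the knockout libraries, a mean of 37.3% ± 1.13 (SD, n = 2). miRNA reads, from the short regulators of mRNA, made up 15.1% of the wild type and 24.8% and 30.7% of the knockout libraries, a mean of 27.8% ± 4.17 (SD, n = 2), which is 1.84 times the wild type. rRNA reads made up 29.3% against 25.7% ± 3.24, snoRNA reads 2.97% against 2.41% ± 0.397, and mRNA reads 7.95% against 6.86% ± 2.46 (each the wild type against the knockout mean with SD, n = 2). The tRNA difference of -7.42 percentage points was 6.57 times the knockout SD in size and the miRNA difference of 12.7 points 3.05 times, and neither was tested. The tRNA difference depended on the miRNA reads: among all other reads tRNA made up 52.6% of the wild type, 48.5% of knockout 1 and 55.0% of knockout 2.

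**Figure D1:**
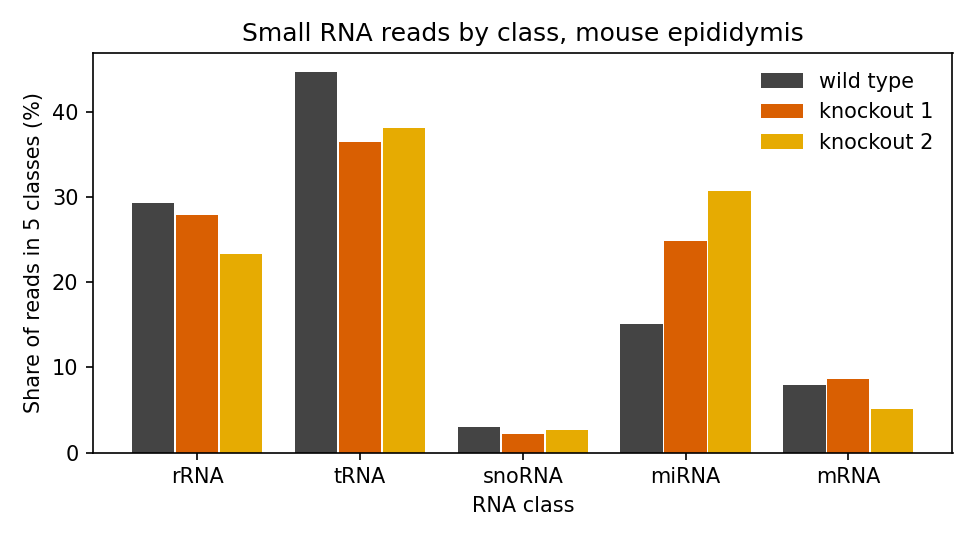
Bars show the share of each library's reads (%, vertical axis from 0) in 5 RNA classes, 1 bar per library. The knockout libraries hold 24.8% and 30.7% miRNA reads against 15.1% in the wild type, and 36.5% and 38.1% tRNA reads against 44.7%.

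The main comparison asked which tRNAs gave more or fewer small RNA reads without ALKBH3. Reads of Glu-CTC, the glutamate tRNA that is the second most abundant source in these libraries, rose from 30918 RPM (reads scaled to the 5-class library total) in the wild type to 56010 ± 2113 (SD, n = 2) in the knockout libraries, a fold of 1.81 (log2 0.86, SE 0.14, adjusted p = 7.4e-06 by edgeR's quasi-likelihood test). Reads of Gly-GCC, the glycine tRNA that gave most reads, fell from 189621 to 130384 ± 3381 (SD, n = 2) RPM, 1.45-fold (log2 -0.54, SE 0.08, adjusted p = 4.9e-07). Among scarce tRNAs, Asn-GTT fell 3.79-fold, from 210 to 55.2 ± 13.7 RPM (log2 -1.92, SE 0.42, adjusted p = 0.00051), and Thr-AGT fell 2.44-fold, from 50.8 to 20.8 ± 1.05 (log2 -1.29, SE 0.30, adjusted p = 0.0013). Arg-TCG fell 1.93-fold, from 19.5 to 10.1 ± 0.394 RPM (log2 -0.95, SE 0.28, adjusted p = 0.0145). As a share of the tRNA table, Glu-CTC stood at 11.6% in the wild type and 25.3% ± 0.273 (SD, n = 2) in the knockout libraries, Gly-GCC at 71.4% and 59.0% ± 0.0607.

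Of 45 anticodons tested, 1 was higher and 4 were lower, and 10 had an unadjusted p under 0.05. The others named by the rule did not pass. Glu-TTC had a log2 fold change of 0.62 (adjusted p = 0.387) and Ala-CGC one of 0.36 (adjusted p = 0.677), while Gly-CCC had -0.62 (adjusted p = 0.066), Val-TAC -0.82 (adjusted p = 0.267) and His-GTG -0.65 (adjusted p = 0.271). Val-CAC (-0.41), Val-AAC (-0.29), Lys-CTT (-0.14) and Asp-GTC (-0.09) lay nearer to 0, and the sign turned positive for Lys-CTT and Asp-GTC with TMM factors, column sums, DESeq2 or a library size without miRNA reads, and for Val-AAC with DESeq2. The median log2 fold change over all anticodons was -0.29, and it shifted by 0.16 with TMM factors, 0.26 with column sums, 0.32 with DESeq2 and 0.25 without miRNA reads in the library size. Relative to that median, Glu-CTC stood at 1.15, Asn-GTT at -1.63, Thr-AGT at -0.99, Arg-TCG at -0.66 and Gly-GCC at -0.25. Over the same 5 scalings, Glu-CTC ranged from 1.14 to 1.16 and Gly-GCC from -0.26 to -0.23. A change of scaling moves all anticodons by nearly the same amount, which the median takes out. These narrow ranges are therefore no sign of stability.

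Without miRNA reads in the library size all 5 calls were lost, Glu-CTC, Gly-GCC and Arg-TCG also without a dispersion trend, Asn-GTT, Thr-AGT and Arg-TCG also with column sums, and Gly-GCC, Thr-AGT and Arg-TCG also with DESeq2. Arg-TCG was also lost with the stricter filter and with per-library table counts. Without miRNA reads the log2 fold changes were 1.10 (SE 0.34) for Glu-CTC, -0.30 (SE 0.25) for Gly-GCC, -1.68 (SE 0.52) for Asn-GTT, -1.05 (SE 0.46) for Thr-AGT and -0.72 (SE 0.44) for Arg-TCG, each with a larger SE than as reported, and the common dispersion was 0.0413 against 0.0302. Without a trend the log2 fold changes stayed and the SE was 0.33 for Glu-CTC, 0.31 for Gly-GCC and 0.33 for Arg-TCG. With the trend, the smaller SE of Glu-CTC and Gly-GCC (0.14 and 0.08) rested on few anticodons of like abundance, themselves included. The adjusted p over the alternatives ranged from 1.2e-12 to 0.104 for Glu-CTC, 2.5e-09 to 0.744 for Gly-GCC, 4.7e-06 to 0.0926 for Asn-GTT (log2 -1.21 with per-library table counts, adjusted p = 0.0344), 3.9e-05 to 0.409 for Thr-AGT and 0.0086 to 0.737 for Arg-TCG, which passed in 3 of 9. The calls were 1 higher and 4 lower as reported, 4 and 7 with TMM factors, 1 and 2 with column sums, 2 and 1 with DESeq2, and 0 and 0 without miRNA reads, where edgeR's quasi-likelihood test left 4 anticodons at an unadjusted p under 0.05. Of those that did not pass as reported, Glu-TTC passed with DESeq2 (adjusted p = 0.0165, up to 0.737 elsewhere) and Gly-CCC in 3 of 9 alternatives (0.0171 to 0.744).

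**Figure D2:**
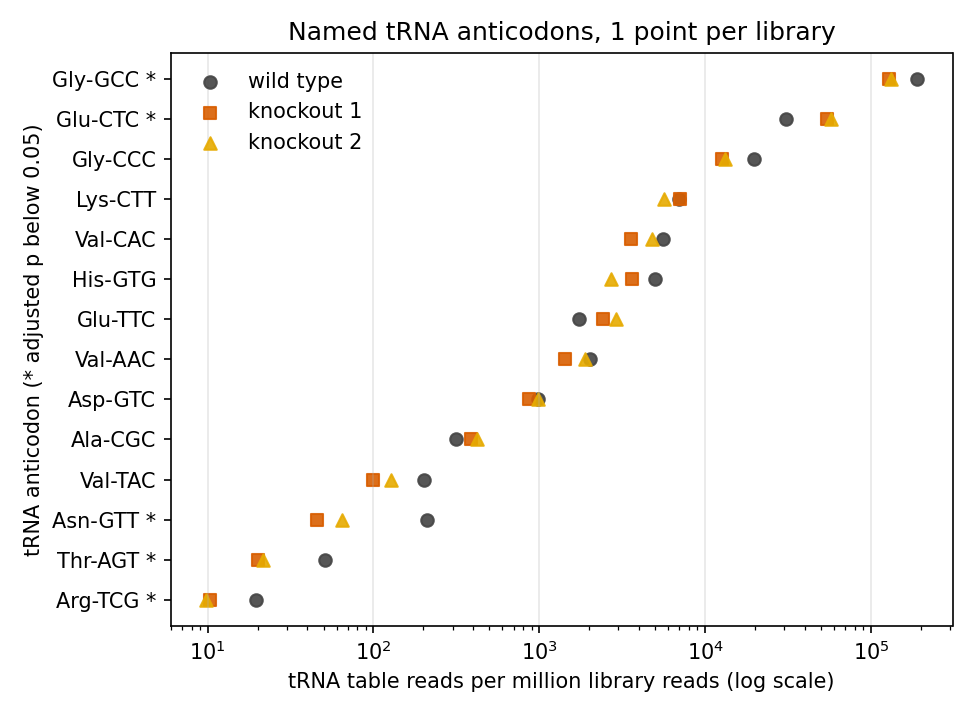
Points show RPM (horizontal log axis) of the 14 tRNA anticodons named by the rule, 1 point per library, with a star for an adjusted p below 0.05. Both knockout libraries lie above the wild type for Glu-CTC (54516 and 57504 against 30918 RPM) and below it for Gly-GCC, Asn-GTT, Thr-AGT and Arg-TCG.

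Lists of tRNAs that share a modification or a structure were fixed in advance, and camera p-values were adjusted over 8 lists. Those with an estimated correlation rest on 1 residual degree of freedom and cannot decide whether a list result holds. Of the tRNAs that carry 3-methylcytidine at position 32, a base ALKBH3 can demethylate, 8 were tested: Thr-AGT fell, none rose and 7 did not pass, with the same 1 lower and 0 higher when adjusted over the list alone. Their members split evenly, 4 fitted above 0 and 4 below, from Ser-AGA at 0.60 to Thr-AGT at -1.29 (camera adjusted p = 0.917, and 0.952 with an estimated correlation). The direction camera gave was up while the list's median was -0.07. No member of this list had an unadjusted p under 0.05 upwards, and DESeq2 called 0 in either direction, with 1 upwards and 1 downwards at an unadjusted p under 0.05. With TMM factors 1 passed upwards and 1 downwards, and with column sums 0 passed, with 2 upwards and 1 downwards at an unadjusted p under 0.05.

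All 5 tRNAs with 3-methylcytidine in the variable loop, Ser-AGA, Ser-CGA, Ser-TGA, Ser-GCT and Leu-CAG, were fitted above 0, with a median of 0.50. Of these, 0 passed the single test, also when adjusted over the list alone. They had to stay above 0 in the other scalings, each of which moved all anticodons upwards, so this is no support. Ser-TGA lay below the wild type in knockout 1 (11.2 against 11.3 RPM). camera gave an adjusted p of 0.036 upwards with the preset correlation, and an adjusted p = 0.878 with an estimated correlation. By edgeR 0 of the 5 had an unadjusted p under 0.05, by DESeq2 2 had one and 0 passed, and with TMM factors 2 passed. The wider list of tRNAs with a long variable arm, those for serine, leucine and selenocysteine, had 9 members tested and 8 fitted above 0, led by Leu-TAA at 0.74 (adjusted p = 0.098) and Ser-AGA at 0.60 (adjusted p = 0.271), with SeC-TCA at -0.41. None passed the single test or when adjusted over the list alone, 1 had an unadjusted p under 0.05, DESeq2 called 0 with 4 at an unadjusted p under 0.05, and 3 passed with TMM factors. Its camera adjusted p was 0.0107 upwards with the preset correlation, and adjusted p = 0.878 with an estimated correlation. The signs were the same in all 5 scalings, which for members above 0 follows from the upward shift and is no support.

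Of 10 tRNAs known as sources of abundant 5′ fragments in sperm and epididymis, Glu-CTC rose, Gly-GCC fell and 8 did not pass. When adjusted over the list alone 1 was higher and 2 were lower, Gly-CCC being added (camera adjusted p = 0.917, and 0.952 with an estimated correlation). Of the 4 tRNAs that carry queuosine in the anticodon, Asn-GTT fell and Asp-GTC, His-GTG and Tyr-GTA did not pass, with 1 lower also when adjusted over the list alone (camera adjusted p = 0.308, and 0.951 with an estimated correlation). All 4 were fitted below 0, except that Asp-GTC was above 0 in the other 4 scalings. Of the 3 substrates of the methyltransferase DNMT2, Gly-GCC fell and Asp-GTC and Val-AAC did not pass, with 1 lower also when adjusted over the list alone (0.308, and 0.952 with an estimated correlation). Of 9 tested tRNAs with A at position 34, a base that can be edited to inosine, Thr-AGT fell and 8 did not pass, with 1 lower also when adjusted over the list alone (0.917, and 0.952 with an estimated correlation), while 1 passed upwards and 2 downwards with TMM factors. The initiator and elongator methionine tRNAs with anticodon CAT had log2 fold changes of -0.15 and -0.29, and 0 of 2 passed with edgeR or DESeq2, at an unadjusted p under 0.05 or when adjusted over the list alone (0.917, and 0.952 with an estimated correlation). For A at position 34 and for methionine, camera's direction was up while the medians were -0.29 and -0.22.

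Single tRNA genes were tested with the limit that reads of near-identical copies cannot be told apart. Such copies are alike in abundance and pool each other's spread, so gene p-values and counts of calls do not rest on independent features. Of 348 genes tested, 11 were higher and 30 lower. Of 14 tested Glu-CTC genes, the 9 of the most abundant group, named Glu-CTC-1, rose 1.80- to 1.83-fold and 5 did not pass. The largest rise was in the glutamate genes tRNA-Glu-TTC-3-2 (chromosome 3, 96387405 to 96387476, minus strand, in an intron of the non-coding Gm17575), from 115 to 372 ± 77.2 (SD, n = 2) RPM (log2 1.69, SE 0.45, adjusted p = 0.0022), and tRNA-Glu-TTC-3-1 (chromosome 3, 96346675 to 96346746, plus strand, in an intron of the non-coding Platr30), from 63.7 to 197 ± 33.2 (log2 1.63, SE 0.49, adjusted p = 0.0106). They passed in 6 of 9 and 7 of 9 alternatives (adjusted p up to 0.0966 and 0.102), both lost with column sums and without miRNA reads. Among the lower genes were 11 of Asn-GTT, 10 of Gly-GCC, 5 of Thr-AGT, and 1 each of Gly-CCC, Ile-AAT, Arg-TCG and Trp-CCA. With counts from the per-library tables only those of Gly-GCC and Gly-CCC still passed.

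In the gene table, the asparagine gene tRNA-Asn-GTT-3-2 (chromosome 2, 18587044 to 18587117, minus strand, in no GENCODE gene) fell most, 7.09-fold, from 75.0 to 10.5 ± 1.79 (SD, n = 2) RPM (log2 -2.83, SE 0.46, adjusted p = 1.1e-06). tRNA-Asn-GTT-3-6 (chromosome 3, 96497781 to 96497854, in no GENCODE gene) fell 4.11-fold, tRNA-Asn-GTT-3-5 (chromosome 3, 96459138 to 96459211, in an intron of Gm10685 on the other strand) 3.51-fold, tRNA-Asn-GTT-3-4 (chromosome 3, 96451425 to 96451498, in an intron of BC107364 on the other strand) 3.47-fold and tRNA-Asn-GTT-3-9 (chromosome 11, 97702449 to 97702522, in no GENCODE gene) 3.43-fold. The most abundant genes, tRNA-Gly-GCC-2-7, tRNA-Gly-GCC-4-1, tRNA-Gly-GCC-2-1 and tRNA-Gly-GCC-2-8, fell 1.47-fold each, from 19822, 19757, 19671 and 19623 RPM in the wild type. Each passed in 6 of 9 alternatives (adjusted p up to 0.963), being lost with DESeq2, without miRNA reads and without a dispersion trend. tRNA-Gly-CCC-5-1 (chromosome 3, 96311254 to 96311324, plus strand, in no GENCODE gene) fell 1.56-fold, from 19291 to 12401 ± 229 (log2 -0.64, SE 0.11, adjusted p = 3.0e-06). It passed in 6 of 9 alternatives (adjusted p up to 0.833), being lost in the same ones. The Gly-CCC sum, nearly the same reads, had a log2 of -0.62 but an SE of 0.23, and did not pass (adjusted p = 0.066 by the same test). tRNA-Gly-CCC-5-1 held 97.7% of the wild-type Gly-CCC reads, and its reads stood at 0.973, 0.923 and 0.918 times those of tRNA-Gly-GCC-2-7 in the wild type and knockout 1 and 2. The shares of 31 nt reads of these genes were 66.8% and 64.9% in the wild type, 60.6% and 56.6% in knockout 1, and 57.9% and 53.9% in knockout 2. Whether its reads can be told from those of Gly-GCC was not analysed here, so its fall is not counted as separate from that of Gly-GCC. The split of 11 higher and 30 lower genes became 9 and 12 with column sums, 12 and 6 with DESeq2, and 0 and 1 without miRNA reads in the library size, where edgeR left 36 genes at an unadjusted p under 0.05. With counts from the per-library tables, 11 were higher and 11 lower, and tRNA-Asn-GTT-3-2 did not pass (log2 -1.32, adjusted p = 0.148, the highest of its 9 alternatives, with 2.8e-15 the lowest), nor did the other 4 Asn-GTT genes named here. In those counts tRNA-Asn-GTT-3-2 no longer fell most, since tRNA-Asn-GTT-3-4 stayed at log2 -1.46 or below in every alternative. In the wild type, Asn-GTT held 3167 reads in the gene table, and 286 first-class and 1240 second-class reads in the per-library tables.

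tRNA reads were next compared by length, as the gel piece spans fragments from a tRNA cut once in the anticodon loop to shorter ones. Reads of 30 to 36 nt, the size of fragments cut in the anticodon loop, made up 94.2% of tRNA reads in the wild type and 91.1% ± 0.669 (SD, n = 2) in the knockout libraries. Reads of 25 to 29 nt made up 4.44% and 6.07% ± 0.579, those of 15 to 24 nt 0.197% and 0.293% ± 0.0627, and those of 37 to 50 nt 1.05% and 2.30% ± 0.0107. With the limit at 28 nt in place of 30, the class below it differed by 0.144 points (1.63 before) and that above by -1.57 (-3.06 before). With Gly-GCC left out of both counts, reads per read of 30 to 36 nt stood at 0.752 and 0.889 times the wild type at 37 to 49 nt. At 50 nt they stood at 0.436 and 0.561 times. As RPM the values were 0.890 and 1.09, and 0.516 and 0.687. Reads of 31 nt alone were 57.7% of the wild type and 46.3% and 46.2% of the knockout libraries, and reads of 33 nt 4.01% against 9.40% and 7.75%. Within Gly-GCC, 31 nt reads were 63.8% in the wild type against 55.5% and 52.7%. Within Glu-CTC, reads of 33 to 36 nt were 25.9% against 44.2% and 33.6%. Of 20 anticodons with at least 1000 reads, the share of 31 nt reads was lower in both knockout libraries in 12 and higher in 2, and the share of 33 to 36 nt reads was higher in 12 and lower in 5. These shares were not tested.

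**Figure D3:**
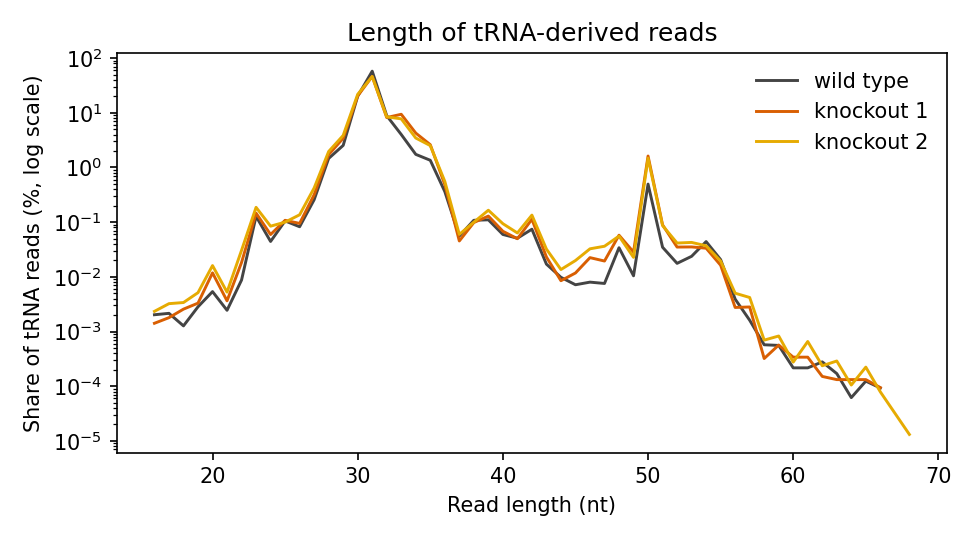
Lines show the share of tRNA reads (%, vertical log axis) at each read length (nt), 1 line per library. The knockout libraries hold 46.3% and 46.2% at 31 nt against 57.7% in the wild type, and 9.40% and 7.75% at 33 nt against 4.01%.

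The fragment test asked which lengths of which tRNA changed. Of 834 features tested, 10 were higher and 8 lower, and 103 had an unadjusted p under 0.05. First-class Glu-CTC reads rose at 34 nt from 1930 to 7314 ± 1565 (SD, n = 2) RPM (log2 1.92, SE 0.32, adjusted p = 2.8e-06), at 33 nt from 7814 to 19982 ± 3136 (log2 1.35, SE 0.27, adjusted p = 0.00017) and at 35 nt from 2531 to 6102 ± 506 (log2 1.27, SE 0.32, adjusted p = 0.0061), while at 31 nt they were 21215 against 31315 ± 5975 and did not pass (log2 0.56, adjusted p = 0.248). The 34 nt and 35 nt features were named after their values were seen. First-class Gly-GCC reads fell at 31 nt from 198278 to 114206 ± 1017 (log2 -0.80, SE 0.17, adjusted p = 0.0006) and did not pass at 30 nt (log2 -0.30, adjusted p = 0.569) or 32 nt (log2 -0.59, adjusted p = 0.218). Second-class Glu-TTC reads of 22 nt rose from 6.95 to 49.8 ± 20.6 RPM (log2 2.84, SE 0.69, adjusted p = 0.0048), and first-class Glu-TTC reads of 50 nt from 1.99 to 12.9 ± 3.32 (log2 2.69, adjusted p = 0.034). These passed in 7 of 8 and 5 of 8 alternatives (adjusted p up to 0.0570 and 0.0835).

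Second-class Asn-GTT reads fell at 36 nt (log2 -2.98, SE 0.63, adjusted p = 0.0006), at 35 nt (log2 -2.77, SE 0.62, adjusted p = 0.0011) and at 39 nt (log2 -2.69, SE 0.80, adjusted p = 0.037, passing in 2 of 7 alternatives, up to 0.164), and second-class Thr-AGT reads at 36 nt (log2 -2.23, SE 0.63, adjusted p = 0.029, passing in 4 of 7, up to 0.165). First-class Val-TAC reads of 50 nt fell from 10.1 to 1.34 ± 0.0283 (SD, n = 2) RPM (log2 -2.90, SE 0.63, adjusted p = 0.0006). Second-class Thr-TGT reads of 34 nt rose from 0.397 to 3.96 ± 2.48 (log2 3.30, SE 0.86, adjusted p = 0.0103) and passed in 5 of 7 alternatives (adjusted p up to 0.0835). Without knockout 2 the log2 ratio with a prior count of 2, which also shrinks it, was 2.18. At 38 nt, a feature outside the naming rule, second-class Thr-TGT reads fell from 7.02 to 1.69 ± 0.454 (log2 -2.06, SE 0.63, adjusted p = 0.0497, passing in 2 of 7 alternatives). As ratios of the same kind, leaving out knockout 2 gave -3.68 for Asn-GTT at 36 nt and -3.43 at 35 nt, and leaving out knockout 1 gave -2.38 at 36 nt. Second-class Leu-TAA reads of 47 nt were 1 in the wild type and 64 in the knockout libraries (ratio of RPM 26.4, counting interval 4.58 to 1060), and second-class Ala-TGC reads of 52 nt were 2 and 73 (ratio 15.1, interval 4.03 to 127), of which 14 lay in knockout 1 and 59 in knockout 2. As log2 ratios with a prior count of 2, Leu-TAA stood at 3.25 without knockout 2 and 3.43 without knockout 1 (4.57 fitted to all libraries), and Ala-TGC at 2.04 and 3.55 (3.75). They passed in 4 of 7 and 3 of 7 alternatives (adjusted p up to 0.0835 and 0.144). The calls of 10 higher and 8 lower became 37 and 16 with TMM factors, 32 and 5 with column sums, 22 and 6 with DESeq2, and 7 and 3 without miRNA reads in the library size. Asn-GTT at 35 and 36 nt and Val-TAC at 50 nt passed in all alternatives that tested them, the Glu-CTC calls at 33, 34 and 35 nt were lost without a dispersion trend (adjusted p up to 0.444, 0.196 and 0.472), and the 31 nt Gly-GCC call was lost in 4 of 8 alternatives (1.7e-17 to 0.680).

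**Figure D4:**
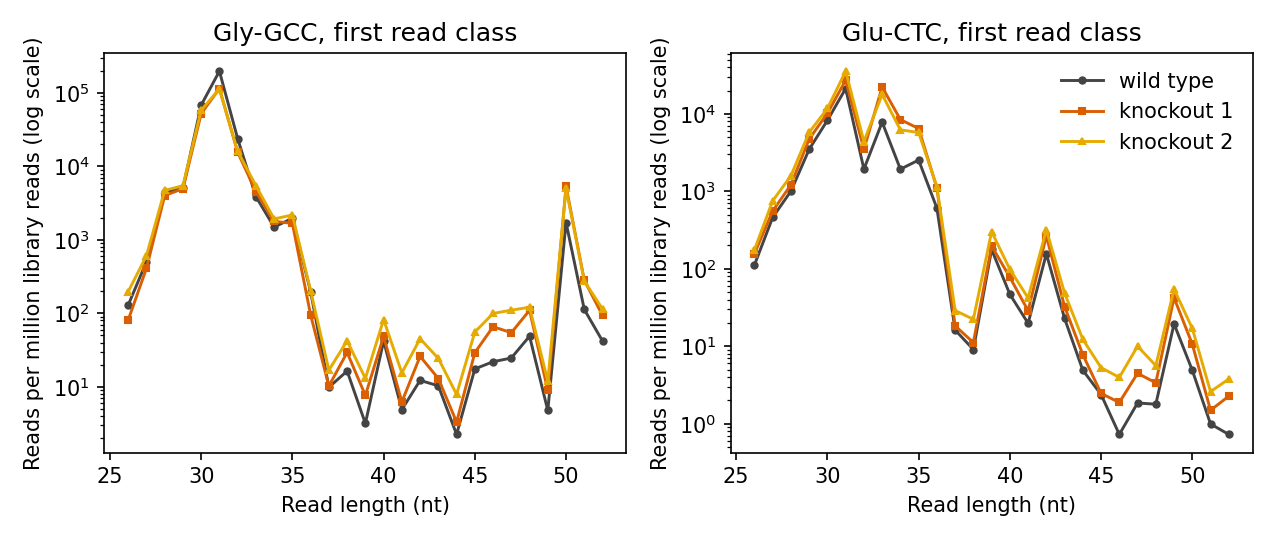
Lines show first-class RPM (vertical log axis) of Gly-GCC and Glu-CTC at each read length (nt), 1 line per library. Gly-GCC is lower in both knockout libraries at 31 nt (114925 and 113486 against 198278) and Glu-CTC is higher at 34 nt (8421 and 6208 against 1930).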

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

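All tests of explanations below were chosen after the results were seen. The miRNA reads and the tRNA reads beyond the cut size were set aside for a closer look because both knockout libraries lay above the wild type there, while rRNA and snoRNA reads lay below it in both and mRNA reads were split. miRNA reads made up 24.8% and 30.7% of the knockout libraries against 15.1% of the wild type. tRNA reads of 51 nt and longer, beyond the size cut from the gel, made up 0.217% and 0.240% of tRNA reads in the knockout libraries against 0.149% in the wild type.

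A larger miRNA share in both knockout libraries could come from a gel piece that reached further into short RNA, from fewer tRNA reads, or from more miRNA in the tissue. A gel piece reaching further down would raise tRNA reads of miRNA length as much as miRNA reads, but tRNA reads of 20 to 24 nt per read of 30 to 36 nt stood at 1.54 times the wild type (1.31 and 1.78 in knockout 1 and 2), below the 2.31 times of miRNA reads (2.11 and 2.52). A loss of tRNA reads alone would leave the ratio of miRNA to rRNA, snoRNA and mRNA reads as it was, and this ratio was 2.17 times the wild type. The ratio to the other classes argues against fewer tRNA reads as the whole cause. The gel piece stays open, since single lengths of the band differed. As shares of tRNA reads, 20, 21, 22, 23 and 24 nt stood at 2.60, 1.82, 2.80, 1.30 and 1.62 times the wild type. At 22 nt, second-class Glu-TTC gave 105 of 565 reads in the wild type, 543 of 971 in knockout 1 and 1364 of 2326 in knockout 2. A difference between the genotypes, and one between animals or preparations, stay open, the first untested beyond this.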

How the results depend on the processing

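The fits without miRNA reads in the library size, without a dispersion trend and with per-library counts were chosen after seeing the data. Over the tested alternatives, 97 of 126 values of named anticodons, 96 of 135 of named genes and 84 of 113 of named fragments kept direction and side of the threshold. Only 5 of the 14 named anticodons, 15 of 15 genes and 12 of 15 fragments were calls, so many of the kept anticodon values are of tRNAs never called. A call was lost in 16, 39 and 26 of the values. The cause of the differences below was not tested. Anticodon calls, 1 higher and 4 lower, were 4 and 7 with TMM factors, 2 lower with column sums, 2 and 1 with DESeq2, 7 lower with a robust prior, 0 and 0 without miRNA reads (edgeR, 4 at an unadjusted p under 0.05), and 0 and 2 without a trend (edgeR, 11 unadjusted). Gene calls, 11 and 30, had 12 lower with column sums, 6 lower with DESeq2, 11 lower with per-library counts, 0 and 1 without miRNA reads (edgeR, 36 unadjusted), and 2 higher without a trend. Fragment calls, 10 and 8, were 37 and 16 with TMM factors, 32 and 5 with column sums, 22 higher with DESeq2, 5 and 4 with no filter, 3 lower without miRNA reads, and 0 and 3 without a trend (edgeR, 99 unadjusted). The log2 fold change turned positive for Lys-CTT (0.040 with TMM factors, 0.13 with column sums, 0.20 with DESeq2, 0.093 without miRNA reads), Asp-GTC (0.077, 0.17, 0.23 and 0.15 in the same order) and Val-AAC (0.032 with DESeq2). The lists with 3-methylcytidine in the variable loop and with a long variable arm had a camera adjusted p of 0.878 each with an estimated correlation. That estimate rests on 1 residual degree of freedom, so the loss decides nothing about these lists. The mean log2 ratio of tRNA reads, -0.26 per all reads, was -0.065 per rRNA, 0.047 per snoRNA, -1.14 per miRNA, -0.0015 per mRNA and -0.027 per all reads but miRNA. With the 30 to 36 nt class widened to begin at 28 nt, the knockout minus wild-type difference was -1.57 percentage points for it (-3.06 before) and 0.144 points for the class below (1.63 before). Leaving out 1 knockout library gives 1 library against 1, which leaves no residual degree of freedom and no test. Between these fits, 2 to 4 anticodons were at least 2-fold lower (2 with all libraries), and 95 to 171 fragments lower (105) and 97 to 169 higher (141). No paired analysis was possible because the wild type has 1 library and no number of its own. The simulated test called 3.45% of 2-fold fragment changes against 40% for anticodon sums, and how much of this is due to depth was not separated from the larger dispersion (0.124 against 0.0302) or the number of features (834 against 45).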

Other observations

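The tests of explanations in this part were chosen after the results were seen. Across amino acids, all tested anticodons of serine (4), leucine (4), alanine (3), proline (3) and glutamate (2) were fitted above 0 and all of threonine (3), arginine (4) and glutamine (2) below 0, with the same signs in 5 scalings. For those above 0 this had to be so, since the other scalings moved all anticodons upwards. Knockout 2 alone lay below the wild type for all 3 of proline, and knockout 1 alone for Ser-TGA and Ala-TGC. Of all these anticodons, Glu-CTC, Thr-AGT and Arg-TCG passed the test. By read class, Asn-GTT was lower in second-class reads, 82.1 against 27.9 ± 11.8 (SD, n = 2) RPM, and 18.9 against 15.6 ± 4.53 in first-class reads. Thr-AGT stood at 68.6 against 27.7 ± 1.83 and Trp-CCA at 31.2 against 15.5 ± 0.578 in second-class reads. In the other direction, second-class reads of Glu-TTC stood at 41.7 against 144 ± 33.7 and those of Leu-TAA at 4.63 against 15.96 ± 1.19. The read class totals and the difference between read classes were not tested.

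The rise of Glu-CTC beside the fall of Gly-GCC could come from the library-size denominator, from the way the authors counted reads per gene, or from a different recovery of fragments by length. With a library size without miRNA reads, Gly-GCC went from log2 -0.54 (SE 0.08) to -0.30 (SE 0.25, adjusted p = 0.744) and Glu-CTC from 0.86 (SE 0.14) to 1.10 (SE 0.34, adjusted p = 0.0547), as the values shifted and the common dispersion went from 0.0302 to 0.0413, so the denominator stays open as the source of the fall. The ratio of Glu-CTC to Gly-GCC reads, which no library size can change, was 0.163 in the wild type and 0.426 and 0.433 in the knockout libraries. In the per-library tables, which sum to another part of the tRNA class, its fold was 2.63. Whether those were counted separately is not given in the sources used here, so this argues only against counting steps that differ between the tables. Among reads of 1 length the fold was 1.42 to 3.07 at the 8 lengths from 28 to 35 nt, which argues against the recovery as the whole cause. With 1 wild-type library, a difference between animals or preparations other than the genotype cannot be told apart from an effect of Alkbh3. Among the column labels only that of the wild type holds what may be a strain name, B6, so a difference in strain background cannot be told apart either. The 3 arrangements of the libraries are too few for a share under 0.05: 1 arrangement, the real one, gave 5 anticodon, 41 gene and 18 fragment calls, against at most 0, 0 and 1 in the others.

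First-class Gly-GCC reads of 50 nt rose from 1725 to 5201 ± 223 (SD, n = 2) RPM (log2 1.59, adjusted p = 0.00058 by edgeR's quasi-likelihood test), a feature singled out after its value was seen, whose call was lost without a dispersion trend (adjusted p = 0.330, the highest of 8 alternatives, with 4.0e-07 the lowest). A gel piece reaching further into long RNA could raise them, but it would raise 50 nt reads of other tRNAs too, and these together stood at 0.601 times the wild type (0.649 also without Lys-CTT, the largest of them). Of 11 other anticodons with at least 100 reads of 50 nt, 8 were lower in both knockout libraries and 3 higher in both, namely Glu-TTC (5.33 and 7.71 times), Glu-CTC (2.17 and 3.47) and Gly-CCC (1.18 and 1.24), which argues against the gel piece as the whole cause. Per read of 30 to 36 nt, all tRNA reads of 51 nt and longer had a knockout mean of 1.59 times the wild type and those of 37 to 49 nt 1.41 times, higher in both knockout libraries. With Gly-GCC left out of these reads and of the 30 to 36 nt reads, both were lower, at 0.604 and 0.730 and at 0.752 and 0.889 in knockout 1 and 2. As RPM, reads of 51 nt and longer without Gly-GCC stood at 0.715 and 0.894, while those of 37 to 49 nt were split at 0.890 and 1.09, so their fall depended on the denominator. Gly-GCC reads of 46 to 49 and 51 to 53 nt stood at 2.68 times. A difference between the genotypes and one between preparations stay open and were not tested.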
